A study of Homo sapiens with 10 samples.

How the data were processed

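Total RNA from 10 samples of esophageal squamous carcinoma cells was measured by sequencing of Ovation Solo libraries, 48 h after transfection. There were 4 groups, namely KYSE-410 with siCT (3 libraries) or siSHIP2 (3) and KYSE-30 with siCT (2) or siSHIP2 (2). Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.5.3a and counted per gene with HTSeq. The deposited table gives CPM (counts per 1 M counts) for 58302 genes, 20208 of them at 0 in all libraries. Values of each library are whole multiples of 1 step, and the pattern of missing whole numbers points to counts that were scaled to about 20 M and rounded up before conversion. No header or note states this, so it is an inference from the values. The recovered whole numbers, and reads with the rounding undone, served only alternatives and checks. The estimated total before that scaling was 18.5 M to 25.8 M reads per library. The floor was set at 3 of the scaled counts, about 0.15 CPM. Positions were taken from GENCODE 29 (GRCh38), which holds 58039 of the gene identifiers.

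The plan for counts was an edgeR test and for normalized values limma-trend, and the latter was used because the unit is CPM. Genes with at least 0.5 CPM in at least 2 libraries were tested (20466). With limma 3.58.1 in R 4.3.3, log2(CPM + 1) was fitted with 4 group means over all 10 libraries, so that the KYSE-30 groups share the estimate of the spread with KYSE-410, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Contrasts were siSHIP2 against siCT in each line, the difference of these between lines (interaction), their average, and KYSE-410 against KYSE-30 with siCT. Calls shared by the lines were compared with the number independent lists would share, by a one-sided Fisher's exact test.

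Fixed gene lists (39, of which 38 had at least 5 measured members) were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone. Samples, comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule names INPPL1 first. For each line it takes the 10 higher and 10 lower genes with the largest fold change among called genes whose mean is above the median of tested genes (14.1 CPM), whose replicates do not overlap and which have an approved-style symbol. It takes 8 per direction for both lines and for the lines with siCT, 6 per direction for the interaction, and up to 4 called members of each list with the smallest adjusted p. Genes fixed in advance, among them INPP5D, PLK1, AKT1, CDKN1A and CDKN1B, are named whatever their p.

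The alternatives were relative log expression and upper quartile scaling, DESeq2 1.42.0, no filter, a filter of 10 CPM, a pseudocount of 0.1, each line alone, the replicate number as a block, a test against a fold change of 1.5, and leaving out each library. TMM scaling and edgeR 4.0.16 on the recovered whole numbers and on reads with the rounding undone were added after the data were seen. Short sequences in 3' untranslated regions were scanned in 12170 genes with an annotated region and a mean of at least 2 CPM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The procedure was tested on simulated data with planted changes. Recovery moved with the random seed. Over 11 simulations limma recovered a median of 80% (72% to 88%) of genes planted at 2-fold in KYSE-410, 67% (57% to 82%) in KYSE-30 and 66% (56% to 73%) for the interaction, with at most 12, 14 and 8 false calls. At 1.25-fold the medians were 31%, 17% and 4%. A planted list of 30 members at 1.25-fold was found by camera with either correlation (adjusted p = 2.01e-70 and 0.000161), with 0 other lists past the threshold. Its members came from the list of G2/M and mitosis, whose estimated correlation was 0.686 in the data. Simulated genes were drawn independently, so how camera does with correlated members was not tested. Samples of the other siRNA against INPPL1 are not held in the table and were not used here.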

Results

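Total RNA was sequenced from 2 human esophageal squamous cell carcinoma lines, KYSE-410 and KYSE-30, collected 48 h after transfection with a small interfering RNA (siRNA). The siRNA called siSHIP2 targets INPPL1, the gene of SHIP2, a phosphatase that acts on the membrane lipid phosphatidylinositol trisphosphate made by PI3K. The control, siCT, is a non-targeting siRNA. KYSE-410 had 3 libraries per treatment and KYSE-30 had 2. Another siRNA against INPPL1 in KYSE-410, named in the description of the series, was not analysed here. The labels number the replicates without saying whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical. The table gives CPM (counts per 1 M counts) for 58302 genes, and each library has values above 0 for 26636 to 28623 of them. The number of reads assigned to genes, estimated from the whole numbers missing among the scaled counts, was 18.5 M to 25.8 M per library. The floor was set at 3 of the scaled counts, about 0.15 CPM. The 10 most abundant genes took 2.69% to 3.11% of each library. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes at low levels. The first principal component of that scale held 90.2% of the variance and separated the lines, and the next held 6.4% and separated siSHIP2 from siCT in KYSE-410.

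The first question was what loss of SHIP2 does to the transcriptome of KYSE-410. INPPL1 itself (ENSG00000165458, chromosome 11, 72223701 to 72239105, plus strand, GRCh38) stood at 107, 108 and 109 CPM in the 3 siCT libraries and at 44.7, 37.3 and 39.1 CPM in the 3 siSHIP2 libraries. Its mean fell from 108 ± 1.16 to 40.4 ± 3.89 CPM (SD, n = 3), which is 37.4% of the control (log2 fold change -1.4, SE 0.067, limma adjusted p = 5.81e-10). Every siSHIP2 library of KYSE-410 lay below every siCT library. INPP5D, the gene of the related phosphatase SHIP1, was at or under the floor of 3 scaled counts in KYSE-410, so no fold is given. It was at 0.1 ± 0.05 CPM with siCT and 0.0167 ± 0.0289 CPM with siSHIP2.

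**Figure D1:**
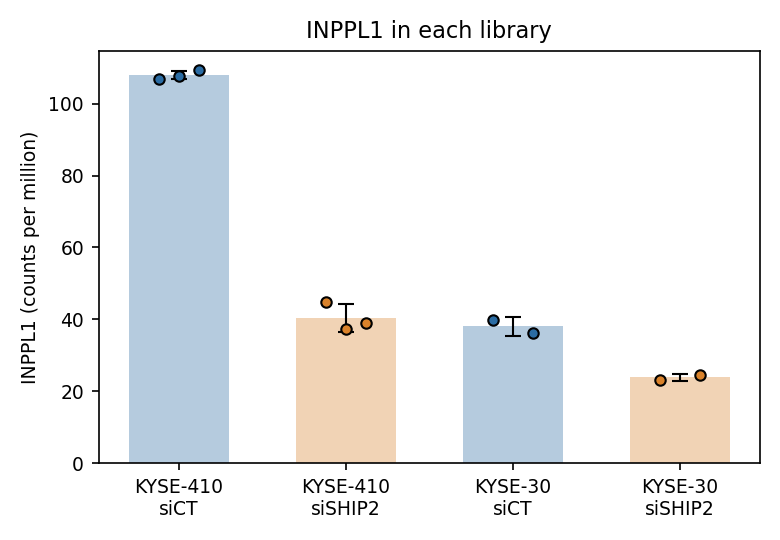
INPPL1 in CPM (vertical axis, from 0) in each library (points), with the mean of each group (bars) and its standard deviation (error bars), for 3 libraries per treatment in KYSE-410 and 2 in KYSE-30. Siblings of one group lie close together, and the siSHIP2 libraries lie below the siCT libraries in both lines, at 37.4% of the control mean in KYSE-410 and 62.8% in KYSE-30.

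Among called genes with a mean above 14.1 CPM over the 10 libraries and replicates that do not overlap, KLHL24 rose most in KYSE-410. KLHL24 (ENSG00000114796, chromosome 3, 183635568 to 183684477), a substrate adaptor of a ubiquitin ligase, went from 10.6 ± 1.38 to 74.5 ± 5.66 CPM (SD, n = 3, log2 2.70, SE 0.107, limma adjusted p = 1.67e-10). CALCOCO1, an autophagy receptor, rose from 12.6 to 63.7 CPM (log2 2.25), PBXIP1, a partner of PBX transcription factors, from 11.8 to 58.9 CPM (2.23), and PNRC1, a nuclear receptor coactivator, from 6.46 to 33.8 CPM (2.22). SGK1, a kinase related to AKT, rose from 1.42 ± 0.236 to 10.6 ± 3.45 CPM (2.23). The autophagy regulator TP53INP2, the actin nucleator JMY, the pro-apoptotic gene BMF and the transcriptional regulator CITED2 rose by log2 1.88, 1.81, 1.77 and 1.76, and the transcription factor SOX4 rose from 140 ± 6.96 to 448 ± 19.4 CPM (1.67).

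Among the genes that fell most in KYSE-410, AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase, went from 177 ± 7.05 to 43.8 ± 5.3 CPM (log2 -2.00, SE 0.085, adjusted p = 3.24e-10). The natriuretic peptide receptor gene NPR3 fell from 33.5 to 8.53 CPM (-1.88), the transglutaminase gene TGM2 from 168 ± 11.3 to 51.0 ± 21.2 CPM (-1.77), and PSIP1, which encodes the chromatin protein LEDGF, from 88.4 ± 3.18 to 26.0 ± 4.28 CPM (-1.74). The carbonic anhydrase gene CA12 fell from 47.2 to 14.4 CPM (-1.67) and the glutathione peroxidase gene GPX2 from 257 to 81.9 CPM (-1.64). TXNDC12, a thioredoxin-domain gene, CPNE2, LAPTM5 and SLC37A2 fell by log2 1.65, 1.64, 1.54 and 1.46. The rule that picked these genes required a mean above 14.1 CPM over the 10 libraries and replicates that do not overlap.

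**Figure D2:**
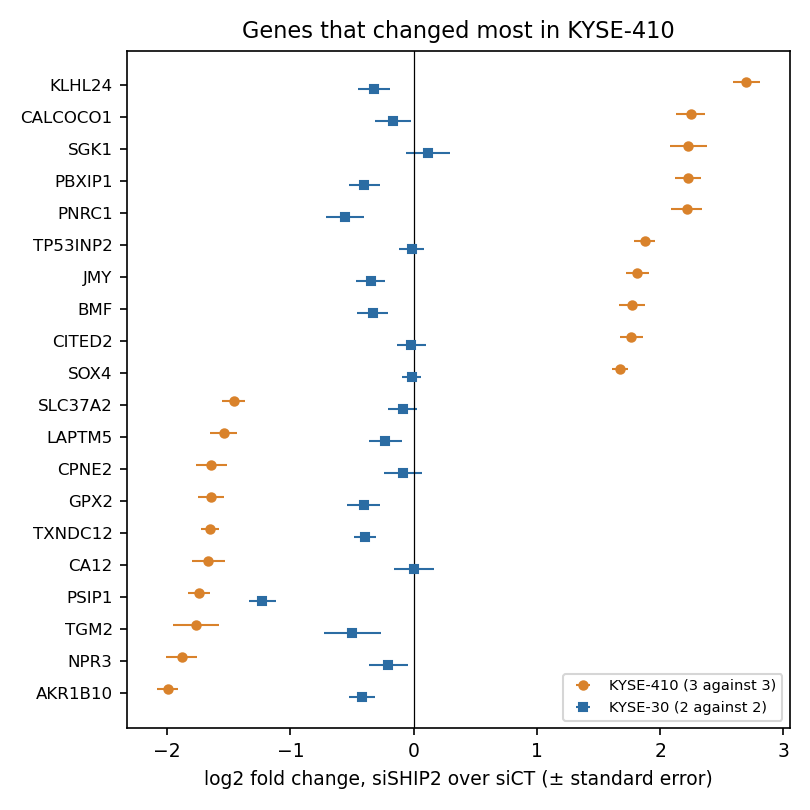
Log2 fold change of siSHIP2 over siCT (horizontal axis, on the log2(CPM + 1) scale) of the 10 higher and 10 lower genes that changed most in KYSE-410 (vertical axis) by the rule for named genes. That rule takes called genes with a mean above 14.1 CPM over the 10 libraries and replicates that do not overlap. Circles give KYSE-410 with 3 libraries against 3 and squares give KYSE-30 with 2 against 2, with bars of 1 standard error. In KYSE-30 PSIP1 lies farthest from 0, at -1.23, and KLHL24 lies on the other side of 0, at -0.32.

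Genes of late cell cycle fell together in KYSE-410. Of 35 measured genes of G2/M and mitosis, 31 fell and none rose, with 31 lower and 1 higher when adjusted over the list alone (median log2 -0.37, camera adjusted p = 5.74e-14, but adjusted p = 0.446 with an estimated correlation). PLK1, a kinase of mitotic entry, fell from 165 ± 8.08 to 94.4 ± 11.8 CPM (log2 -0.80, SE 0.071, adjusted p = 1.98e-07), the survivin gene BIRC5 by log2 1.03, the centromeric histone gene CENPA by 0.87 and the spindle gene HMMR by 0.92. Genes of G1/S and DNA replication were split, with 13 higher and 9 lower of 37 (13 and 9 when adjusted over the list alone), but 7 and 14 with TMM, 8 and 14 with relative log expression and 10 and 12 with upper quartile scaling, so they have no direction. Their median was 0.04 while camera, which ranks them against other genes, put them on the low side (adjusted p = 0.969). The cell cycle inhibitor CDKN1B rose from 61.6 ± 1.92 to 95.6 ± 5.34 CPM (log2 0.62, adjusted p = 1.11e-06), whereas CDKN1A fell by 0.27 (adjusted p = 0.000168).

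Growth and metabolic groups also fell in KYSE-410. Of 30 genes of the list of MYC targets and ribosome biogenesis, 22 fell and 1 rose, with 23 and 1 when adjusted over the list alone (median -0.25, camera adjusted p = 5.94e-08, adjusted p = 0.446 with an estimated correlation). The nucleolar genes NOP58, RRP9, BOP1 and DKC1 fell by log2 0.75, 0.69, 0.51 and 0.50. Of 28 targets of NRF2, the transcription factor of the oxidative stress response, 20 fell and 2 rose, and the same numbers held when adjusted over the list alone (median -0.38, camera adjusted p = 7.05e-09, adjusted p = 0.446 with an estimated correlation). Besides AKR1B10 and GPX2 these included UGDH (log2 -0.86) and the transporter ABCC3 (-0.89). Of 29 genes of cholesterol synthesis and its regulator SREBP, 17 fell and 3 rose, also when adjusted over the list alone (median -0.31, camera adjusted p = 5.67e-05, adjusted p = 0.446 with an estimated correlation). The fatty acid synthase gene FASN fell by 0.76 and the sterol enzyme gene LSS by 0.57.

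FOXO targets and genes of lysosomes and autophagy rose in KYSE-410. FOXO transcription factors are held in check by AKT. Of 26 FOXO targets, 19 rose and 1 fell, with 19 and 1 when adjusted over the list alone (median 0.43, camera adjusted p = 1.85e-05, adjusted p = 0.446 with an estimated correlation). CITED2 (log2 1.76), the insulin receptor gene INSR (1.59), KLF6 (1.34) and the muscle-wasting ubiquitin ligase gene FBXO32 (0.82) had the smallest adjusted p of the list. Of 31 genes of lysosomes and autophagy, 23 rose and 5 fell, with 23 and 5 when adjusted over the list alone (median 0.25, camera adjusted p = 0.00234, adjusted p = 0.446 with an estimated correlation). The autophagy genes ULK1, GABARAPL1 and WIPI2 rose by 1.31, 1.26 and 0.62, and the proton pump gene ATP6V0D1 by 0.64. With TMM scaling 15 rose and 6 fell (median 0.13), and with relative log expression 16 and 6 (0.14).

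Groups of adhesion, squamous identity and trafficking leaned lower in KYSE-410 with members on both sides. Of 23 genes of the TGF-beta and BMP response, 12 fell and 4 rose, likewise when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.446 with an estimated correlation). TGFBI, TGFBR2 and TGFB1 fell by log2 1.07, 1.05 and 0.60, and the cell cycle inhibitor CDKN2B rose by 1.08. Of 16 markers of basal squamous cells, 9 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.446 with an estimated correlation). The basement membrane genes COL7A1 (-0.68) and ITGB4 (-0.60) fell and the neurotrophin receptor gene NGFR rose (1.97). Of 28 genes of squamous differentiation, 10 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.446 with an estimated correlation), with KRT6A at -1.57, NOTCH3 at -1.0, PPL at -0.56 and TGM1 at 0.66. Of 33 genes of integrins and focal adhesion, 16 fell and 10 rose, also when adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.686 with an estimated correlation). The actin crosslinker FLNA, the tensin TNS4 and the integrin ITGB5 fell by 0.86, 0.93 and 0.56. With TMM scaling 18 fell and 4 rose (median -0.23 against -0.11).

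Of 26 genes of clathrin-mediated endocytosis, a process SHIP2 takes part in, 10 fell and 5 rose in KYSE-410, also when adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.446 with an estimated correlation). Dynamin 2 (DNM2) and the adaptor AP2A1 fell by log2 1.03 and 0.96, while CBLB and SNX9 rose by 0.84 and 0.41. With TMM scaling 17 fell and 2 rose, with relative log expression 16 and 2, and with upper quartile scaling 14 and 3. Of 22 genes of ER chaperones and the unfolded protein response, 10 fell and 5 rose, with 11 and 5 when adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.446 with an estimated correlation), among them CALR (-0.69), SDF2L1 (-0.88), PDIA4 (-0.50) and HERPUD1 (0.60), and 15 fell and 3 rose with TMM scaling (median -0.23 against -0.11). The lists closest to the target moved both ways. Of 25 phosphoinositide phosphatases, 8 rose and 5 fell (8 and 5 when adjusted over the list alone, camera adjusted p = 0.891), but 7 and 10 did with TMM or relative log expression scaling and 7 and 9 with upper quartile scaling, with MTM1 at 0.62, MTMR3 at 0.53, MTMR14 at 0.41 and INPP5A at -0.55. Of 31 components of PI3K, AKT and mTOR signalling, 11 rose and 11 fell (11 and 11 when adjusted over the list alone, camera adjusted p = 0.891), against 9 and 12 with TMM scaling, with PIK3C3 at 0.78, TSC1 at 0.70, PIK3R3 at 0.69 and AKT1 at -0.26 (adjusted p = 0.000126). The median of the latter list was 0.03, against -0.09 with TMM scaling, and that of the phosphatases 0.08, against -0.03, so neither has a direction. Markers of other cell types did not pass the test in KYSE-410. Among 12 measured markers of glandular epithelium 2 rose and 4 fell (camera adjusted p = 0.235), and among 5 of fibroblasts 1 rose and 2 fell (camera adjusted p = 0.39).

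In all, limma called 10205 of 20466 tested genes in KYSE-410, 6256 higher and 3949 lower, and 239 of the higher and 127 of the lower ones changed by at least 2-fold. The split between higher and lower depends on the scaling, since 61.3% of the calls were higher in the deposited scale and 43.6% to 48.7% were with the other scalings and count tests. Against a fold change of 1.5 the count was 486, 282 higher and 204 lower.

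The same siRNA was given to KYSE-30, to ask the same question in another line. INPPL1 stood at 39.9 and 36.2 CPM in the siCT libraries and at 23.2 and 24.5 CPM in the siSHIP2 libraries. The mean fell from 38.0 ± 2.61 to 23.9 ± 0.93 CPM (SD, n = 2), or 62.8% of the control (log2 -0.65, SE 0.082, limma adjusted p = 0.00077). Leaving out siCT replicate 1 or siSHIP2 replicate 1 of KYSE-30 took the adjusted p to 0.0585 and 0.0607, and fitting KYSE-30 alone took it to 0.336. INPP5D was close to the floor at 0.525 ± 0.0354 and 0.475 ± 0.177 CPM.

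Among called genes with a mean above 14.1 CPM over the 10 libraries and replicates that do not overlap, those that rose most in KYSE-30 were SPOCD1, from 2.25 ± 0.989 to 4.65 ± 0.638 CPM (log2 0.83, SE 0.155, adjusted p = 0.0155), the lipid hydrolase gene NCEH1 (ENSG00000144959, chromosome 3, 172630249 to 172711218), from 90.3 ± 12.3 to 157 ± 5.86 CPM (0.80, adjusted p = 0.000133), and the protein kinase gene PSKH1, from 28.4 ± 0.103 to 49.2 ± 0.234 CPM (0.77, adjusted p = 0.000152). FSTL3, which binds activin, SMIM13, the interferon-induced gene IFI44, the glycosyltransferase gene GALNT5, the transcriptional repressor NACC2, the chondroitin synthesis gene CHPF and ZBTB45 rose by log2 0.69, 0.64, 0.63, 0.61, 0.56, 0.53 and 0.50. By the same rule the largest fall was that of PSIP1 (ENSG00000164985, chromosome 9, 15464066 to 15511019), from 62.2 ± 2.83 to 26.0 ± 1.67 CPM (-1.23, SE 0.108, adjusted p = 9.59e-05). The transmembrane gene SLITRK6 fell from 11.1 ± 3.71 to 4.35 ± 0.638 CPM (-1.15), the matrix gene TNC, tenascin C, from 53.1 ± 9.96 to 24.0 ± 1.97 CPM (-1.1), and CREG1 from 85.8 ± 8.82 to 49.3 ± 7.33 CPM (-0.79). SSBP3, the phosphatase gene PTPRR, the cyclin gene CCNG2, the secretory protein gene AGR2, the desmosomal gene DSC2 and MAP2 fell by 0.94, 0.94, 0.78, 0.76, 0.74 and 0.71.

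Genes of G1/S and DNA replication lay higher in KYSE-30. Of 37 measured, 5 rose and none fell, with 13 higher when adjusted over the list alone (median 0.14, camera adjusted p = 6.16e-09, adjusted p = 0.567 with an estimated correlation), and 2 were called with TMM scaling. The ribonucleotide reductase gene RRM2 rose by log2 0.37, E2F1 by 0.45, E2F2 by 0.43 and CDC6 by 0.24. Of 30 genes of MYC targets and ribosome biogenesis, 3 rose and none fell, with 7 higher when adjusted over the list alone (median 0.16, camera adjusted p = 6.19e-09, adjusted p = 0.567 with an estimated correlation), namely BOP1 (0.29), the polyamine enzyme ODC1 (0.33) and PPAN (0.31). With TMM scaling limma called 0 of the 30 (2 with relative log expression, 3 with upper quartile scaling). Of 26 FOXO targets, 5 fell and none rose, with 7 lower when adjusted over the list alone (median -0.11, camera adjusted p = 0.000805, adjusted p = 0.663 with an estimated correlation), among them CCNG2, the thioredoxin inhibitor TXNIP (-0.58), the catalase gene CAT (-0.33) and RBL2 (-0.30), but 1 was called with TMM scaling.

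Of 16 markers of basal squamous cells in KYSE-30, 3 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.567 with an estimated correlation). They were the lineage transcription factors SOX2 (log2 -1.04, adjusted p = 0.00348) and TP63 (-0.55, adjusted p = 0.0142) and the integrin ITGA6 (-0.32), and 2 members were called with TMM scaling. Of 23 genes of matrix metalloproteases and plasminogen activators, 2 fell and none rose, with 5 lower when adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.567 with an estimated correlation), which were the inhibitor TIMP3 (-0.52) and MMP9 (-0.55), and 1 was called with TMM scaling. Of 22 genes of ER chaperones and the unfolded protein response, 3 fell, with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.567 with an estimated correlation), namely EDEM1 (-0.26), PDIA3 (-0.23) and PDIA6 (-0.24). With TMM scaling limma called 0 of the 22 (2 with relative log expression, 1 with upper quartile scaling). None of the 35 genes of G2/M and mitosis passed the limma test in KYSE-30, and 1, higher, did when adjusted over the list alone (median 0.04, camera adjusted p = 0.0873). PLK1 was at 218 ± 8.25 and 234 ± 7.0 CPM there (log2 0.10, adjusted p = 0.614). Of the 6 lists that passed camera in KYSE-30, 2 passed without KYSE-30 siCT replicate 1, 4 without siSHIP2 replicate 1 and 5 without siSHIP2 replicate 2, and 0 of the 6 passed with fry (adjusted p = 0.146 to 0.249).

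In KYSE-30 limma called 482 of 20466 genes, 166 higher and 316 lower, of which 6, all lower, changed by at least 2-fold. With KYSE-30 fitted alone the spread comes from 4 libraries, and limma called 0 genes (2834 at an unadjusted p under 0.05, lowest adjusted p = 0.336), against 615 with DESeq2 and 481 with edgeR over all 10 libraries. With TMM scaling the count was 160, without KYSE-30 siCT replicate 1 or siSHIP2 replicate 1 it was 16 or 14, without KYSE-410 siCT replicate 1, 2 or 3 it was 233, 213 or 259, and without KYSE-410 siSHIP2 replicate 1 or 3 it was 812 or 278.

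The next question was whether the lines responded with the same genes. PSIP1, SSBP3 (log2 -1.28 in KYSE-410 and -0.94 in KYSE-30), the cofilin gene CFL2 (-1.31 and -0.67), the laminin gene LAMC1 (-1.25 and -0.52), the small GTPase gene RAB15 (-1.04 and -0.66), TXNDC12 (-1.65 and -0.40), AKR1B10 (-2.00 and -0.42) and INPPL1 fell in both lines. PSKH1 (0.91 and 0.77), NACC2 (1.06 and 0.56), WEE1, an inhibitor of mitotic entry (50.1 to 114 CPM in KYSE-410, log2 0.35 in KYSE-30), CHPF (0.83 and 0.53), ZBTB45 (0.74 and 0.50), REXO1 (0.71 and 0.41), TRIB1 (0.78 and 0.34) and NCEH1 (0.32 and 0.80) rose in both. AKR1B10 was scarce in KYSE-30, at 0.874 ± 0.106 CPM with siCT.

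Of the calls, 140 genes were lower in both lines where independent lists would share 61.0 (2.3 times as many, one-sided Fisher's exact test p = 1.53e-24), and 51 were higher in both where 50.7 would be shared (p = 0.512 by the same exact test). The number higher in both depends on the setting, with 15 against 9.2 under TMM, 31 against 23.3 under relative log expression scaling and 8 against 4.1 without a filter. It was 65 against 77.1 with a filter of 10 CPM and 33 against 38.2 with a pseudocount of 0.1. The number lower in both was 57 against 29.5 under TMM. With all 10 libraries it was 1.7 (filter of 10 CPM) to 5.93 times (pseudocount 0.1, no filter) that of independent lists, where both lines had calls. Another 72 were higher in KYSE-410 and lower in KYSE-30, against 96.6 for independent lists, and 41 were lower in KYSE-410 and higher in KYSE-30, against 32.0. Genes are not independent, so these p-values describe the lists. The lines have separate controls. Across the 20466 genes the fold changes of the lines had a Pearson correlation of 0.076 and a Spearman correlation of 0.056, and 51.5% of the genes called in KYSE-410 had the same sign in KYSE-30. The 191 genes shared in direction became 72 with TMM scaling and 0 when each line was fitted alone, since limma then called 0 genes in KYSE-30. Without KYSE-30 siCT replicate 1 they were 11, without KYSE-30 siSHIP2 replicate 1 or 2 they were 9 or 112, without KYSE-410 siCT replicate 1, 2 or 3 they were 90, 80 or 96, and without KYSE-410 siSHIP2 replicate 1 or 3 they were 319 or 103. On the average of both lines limma called 7018 genes, 4177 higher and 2841 lower, and the share of higher calls, 59.5%, was 37.9% to 49.0% with the other scalings and count tests.

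**Figure D3:**
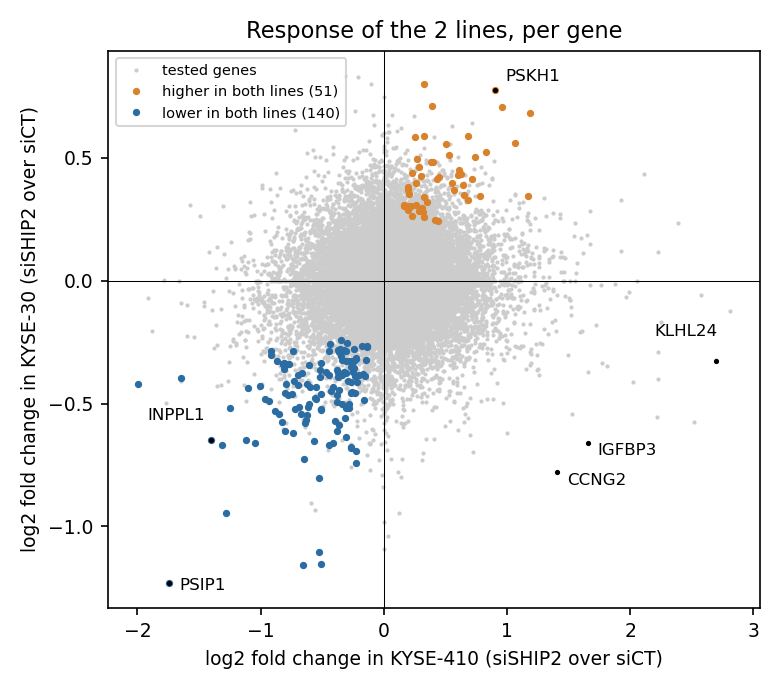
Log2 fold change of siSHIP2 over siCT in KYSE-410 (horizontal axis) and KYSE-30 (vertical axis, with a narrower range) for each of the 20466 tested genes, with the 51 genes higher and the 140 genes lower in both lines coloured and 6 genes named. The cloud has no visible slope (Pearson correlation 0.076), and KLHL24, IGFBP3 and CCNG2 lie to the right of 0 and below it.

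The difference between the lines was tested directly, as the interaction of line and treatment. INPPL1 was reduced more in KYSE-410 (difference of log2 fold changes -0.75, SE 0.105, limma adjusted p = 7.63e-05), from a control level 2.84 times as high. KLHL24 (difference 3.02), PNRC1 (2.77), PBXIP1 (2.63) and CALCOCO1 (2.41) rose in KYSE-410, while their values in KYSE-30 lay below 0 without passing the test (log2 -0.32, -0.56, -0.40 and -0.17). IGFBP3, which binds insulin-like growth factors, rose in KYSE-410 from 23.2 ± 2.76 to 75.2 ± 9.28 CPM and fell in KYSE-30 from 132 ± 32.1 to 82.2 ± 9.65 CPM (difference 2.32, SE 0.184, adjusted p = 7.74e-07). CCNG2 rose in KYSE-410 (1.41) and fell in KYSE-30 (-0.78), a difference of 2.19. On the other side were NPR3 (-1.68), CA12 (-1.67), the transcription factor PITX1 (-1.60), AKR1B10 (-1.58), CPNE2 (-1.55) and the glutathione peroxidase gene GPX3 (-1.54). CA12 is listed at 0 in all KYSE-30 libraries and AKR1B10 is near the floor there, and the differences of both lost their call with DESeq2 and edgeR.

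Gene groups separated the lines as well. Of 35 genes of G2/M and mitosis, 27 had a lower response in KYSE-410 (30 when adjusted over the list alone), with a median difference of -0.45 (camera adjusted p = 8.51e-15, adjusted p = 0.662 with an estimated correlation). PLK1 differed by -0.90 and BIRC5 by -1.06. Of 30 genes of MYC targets and ribosome biogenesis, 22 were lower (26 lower and 1 higher when adjusted over the list alone; median -0.44, camera adjusted p = 6.17e-13, adjusted p = 0.662 with an estimated correlation), and BOP1 and PPAN, which fell in KYSE-410 and rose in KYSE-30, differed by -0.81 and -0.54. Of 26 FOXO targets, 21 were higher and 1 lower (22 and 1 when adjusted over the list alone; median 0.63, camera adjusted p = 1.23e-08, adjusted p = 0.662 with an estimated correlation), such as INSR (1.80) and CITED2 (1.78). Of 28 NRF2 targets, 17 were lower and 1 higher (18 and 2 when adjusted over the list alone; camera adjusted p = 6.94e-07, adjusted p = 0.662 with an estimated correlation). The NRF2 targets AKR1C1, AKR1C2, AKR1C3 and AKR1B10 were absent or scarce in KYSE-30 with siCT, which leaves little room for a fall there and limits the NRF2 result. Of 31 genes of lysosomes and autophagy, 16 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.000925, adjusted p = 0.662 with an estimated correlation), with GABARAPL1 at 1.64.

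Further lists passed the interaction test with members on both sides. Of 29 genes of cholesterol synthesis and SREBP, 14 were lower and 4 higher, also when adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.679 with an estimated correlation), and FASN differed by -1.03. Of 23 genes of the TGF-beta and BMP response, 11 were lower and 5 higher (12 and 6 when adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.662 with an estimated correlation). Of 37 genes of G1/S and DNA replication, 10 were lower and 2 higher (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0245, adjusted p = 0.775 with an estimated correlation), RRM2 among them (-0.51). Of 33 genes of integrins and focal adhesion, 13 were lower and 6 higher, also when adjusted over the list alone (camera adjusted p = 0.0302, adjusted p = 0.775 with an estimated correlation), with FLNA at -1.21. In all, 6627 genes differed in their response, 3993 with the more positive change in KYSE-410 and 2634 with the more negative one. That split, 60.3% positive, was 42.1% to 47.2% with the other scalings and count tests, and 183 genes passed a test against a fold change of 1.5.

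**Figure D4:**
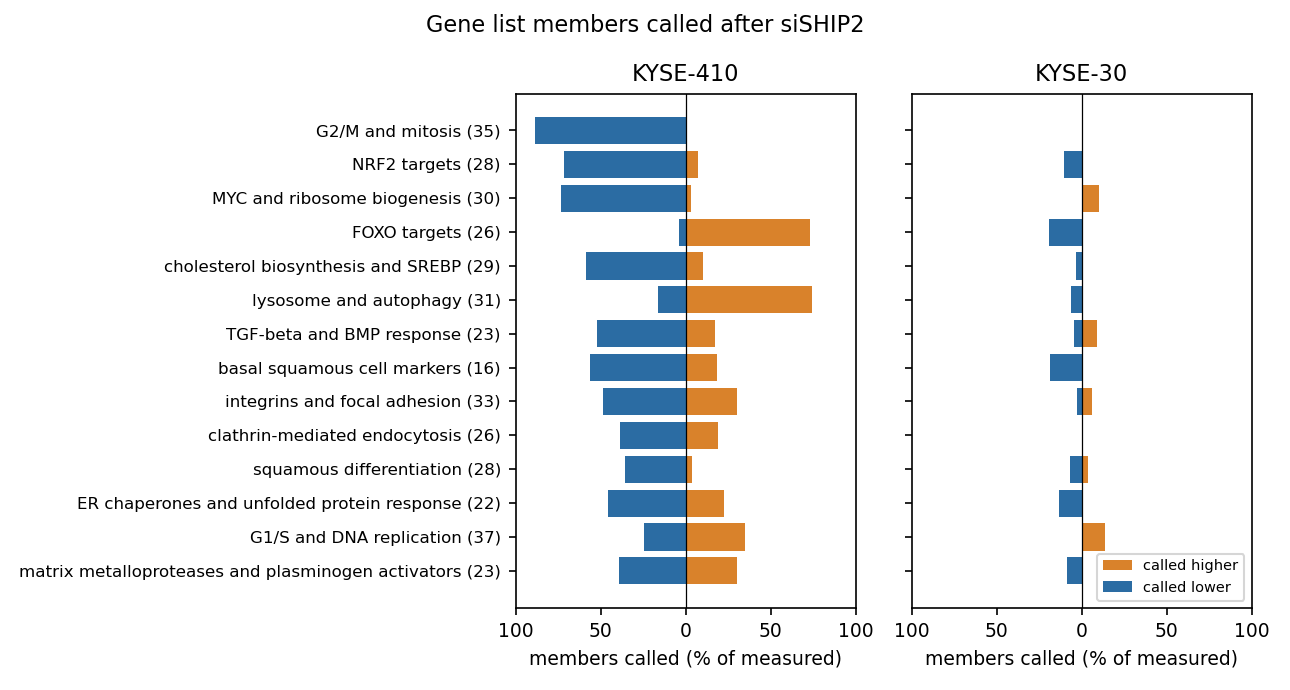
Members of 14 gene lists called higher (right of 0) or lower (left of 0) after siSHIP2, as percent of the measured members (horizontal axis), in KYSE-410 and in KYSE-30, with the number of measured members in brackets. In KYSE-410 31 of 35 genes of G2/M and mitosis were lower and 19 of 26 FOXO targets were higher, and in KYSE-30 none of the former and none of the latter were.

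The lines also differed before SHIP2 was lowered, and siCT libraries gave that background. KYSE-410 expressed the aldo-keto reductases AKR1C2, AKR1C3, AKR1C1 and AKR1B1 at 1278 ± 62.8, 605 ± 26.8, 171 ± 6.14 and 574 ± 23.6 CPM (SD, n = 3), where KYSE-30 had 0.1, 0, 0.175 and 1.85 CPM. Reads of AKR1C1, AKR1C2 and AKR1C3 can be hard to tell apart because the genes are near-identical copies. The thyroid hormone deiodinase gene DIO2 was at 1338 ± 57.0 against 0.15 CPM, the annexin ANXA10 at 280 ± 6.25 against 0.025, the laminin LAMA4 at 203 ± 7.97 against 0.025, and PNMA5 at 197 ± 3.08 against 0. KYSE-30 expressed PEG10 at 931 ± 20.3 CPM against 9.14 in KYSE-410 (SD, n = 2), the peptidylarginine deiminase gene PADI3 at 621 ± 85.2 against 3.70, the collagen gene COL4A2 at 186 ± 4.93 against 0.567, the neurofilament gene INA at 175 ± 2.53 against 0, the glutathione transferase gene MGST1 at 126 ± 2.99 against 0.833, PEBP1 at 117 ± 2.48 against 0.0667, and CPPED1 at 72.9 ± 1.62 against 0.0167.

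With siCT, 26 of 28 NRF2 targets were higher and 2 lower in KYSE-410 than in KYSE-30, also when adjusted over the list alone (camera adjusted p = 6.64e-10, adjusted p = 0.175 with an estimated correlation). Of 23 genes of the TGF-beta and BMP response, 17 were higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.635 with an estimated correlation). Of 20 measured genes of replication-dependent histones, 16 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.000469, adjusted p = 0.175 with an estimated correlation), with reads that near-identical copies may share. Of the 20466 genes, 15539 differed between the lines, 7610 higher and 7929 lower in KYSE-410. Line and any library batch cannot be told apart, because the labels give no batch.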

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

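The test of a smaller INPPL1 reduction was chosen only after the result was seen. The values here are those whose response to siSHIP2 differed between KYSE-410 and KYSE-30 by the interaction test (KYSE-410 minus KYSE-30, log2). The number of such genes was 6627. INPPL1 itself differed by -0.75.

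Many more genes were called in KYSE-410 (10205) than in KYSE-30 (482). The number of replicates is argued against, since the lowest count with 2 KYSE-410 libraries per group, over 9 subsets, was 7339, and so is the scaling, since the lowest ratio of the counts over the other scalings was 19.4. A response in KYSE-30 that follows the KYSE-410 response in proportion to the INPPL1 reduction is argued against by the slope across genes called in KYSE-410, 0.037 (bootstrap over genes 0.028 to 0.045) where the INPPL1 ratio is 0.462. That interval resamples genes, which are not independent, and leaves out the spread between libraries. The ratio has no interval. INPPL1 in KYSE-30 with siSHIP2 (23.2 and 24.5 CPM) lay below every KYSE-410 siSHIP2 library (37.3 to 44.7 CPM), which argues against a level that KYSE-410 reached and KYSE-30 did not. KYSE-30 with siCT already stood about as low as KYSE-410 with siSHIP2. A common level that only KYSE-410 crossed is therefore not argued against. Neither that nor a level particular to each line was tested. A difference between the lines, and a difference in how they were transfected or processed, stay open, because line and any batch cannot be told apart with these labels.

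On the average of both lines 7018 genes were called, and 1 of 60 splits within lines, the real one, gave as many. The highest other split gave 6627 and keeps the real KYSE-410 groups while exchanging those of KYSE-30, so the count is carried by KYSE-410. Every split that keeps the real KYSE-410 groups gave at least 4963, and every split that changes them gave 0. The 60 splits thus add little to those of KYSE-410 alone, and chance is not excluded. In KYSE-410 alone the 10 splits are too few for a share under 0.05, with 10205 genes called by limma in the real split and 0 in the highest other.

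Genes with the more positive change in KYSE-410 were KLHL24 (3.02), PNRC1 (2.77), PBXIP1 (2.63), CALCOCO1 (2.41), IGFBP3 (2.32), CCNG2 (2.19), WEE1 (0.82), CDKN1B (0.74), NACC2 (0.50), TRIB1 (0.44) and REXO1 (0.30). Genes with the more negative change there were NPR3 (-1.68), CA12 (-1.67), PITX1 (-1.60), AKR1B10 (-1.58), CPNE2 (-1.55), GPX3 (-1.54), TXNDC12 (-1.25), PLK1 (-0.90), LAMC1 (-0.73), CFL2 (-0.64), PSIP1 (-0.51), NCEH1 (-0.48), AKT1 (-0.39), RAB15 (-0.38) and CDKN1A (-0.37). The differences of CA12 and AKR1B10 were not called with DESeq2 or either edgeR fit, and both genes are scarce or absent in KYSE-30.

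Gene lists differed by a median of 0.63 (FOXO targets), 0.24 (lysosome and autophagy), -0.45 (G2/M and mitosis), -0.44 (MYC and ribosome biogenesis), -0.37 (NRF2 targets), -0.30 (cholesterol and SREBP), -0.28 (TGF-beta and BMP), -0.06 (integrins and focal adhesion) and -0.05 (G1/S and DNA replication). None of these 9 lists passed camera with an estimated correlation, where the lowest adjusted p was 0.662. Some NRF2 targets were absent or scarce in KYSE-30, which leaves little room for a fall there.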

How the results depend on the processing

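TMM scaling and the edgeR tests were chosen only after the result was seen. INPPL1 in KYSE-410 kept its direction and its call in every setting run. In KYSE-30 INPPL1 kept its direction, but its call ended with the line fitted alone (-0.65, adjusted p = 0.336) and without siCT replicate 1 or siSHIP2 replicate 1 of KYSE-30 (adjusted p = 0.0585 and 0.0607; range -0.72 to -0.58 without 1 library). The KYSE-30 count of 482 became 160 with TMM scaling, 78 without a filter, 83 with a pseudocount of 0.1 and no filter, 71 with the replicate block and, by limma, 0 with the line alone (2834 at an unadjusted p under 0.05) and 0 against a fold change of 1.5 (12 unadjusted), where DESeq2 called 615 and edgeR 481 and 448. Without 1 library it was 14 (KYSE-30 siSHIP2 replicate 1) to 812 (KYSE-410 siSHIP2 replicate 1), with 16 without KYSE-30 siCT replicate 1, 233, 213 and 259 without KYSE-410 siCT replicate 1, 2 and 3, and 278 without KYSE-410 siSHIP2 replicate 3. The 191 genes shared in direction became 72, 31, 40, 33, 0 and 0 in the same settings, in the order TMM, no filter, pseudocount with no filter, block, alone and fold change, and 9 to 319 without 1 library. Leaving out a KYSE-410 library keeps the KYSE-30 fold changes, so the KYSE-30 count then moves only through the shared estimate of the spread. The cause of the other changes was not tested, and fewer samples cannot explain the counts that grew without KYSE-410 siSHIP2 replicate 1 (812 and 319) or 2 (618 and 232). The former library differs more from its siblings (chi-square per gene 7.87 and 6.49) than these from each other (3.26). Against a fold change of 1.5, a stricter question by construction, 486 genes passed in KYSE-410, 183 in the interaction, 10 on the average and 6116 between lines with siCT. A filter of 10 CPM, with fewer genes tested, left 10041 between lines. Of the gene lists, 12, 6, 9 and 3 passed in KYSE-410, KYSE-30, the interaction and between lines with siCT. With an estimated correlation 0 passed in each by camera, and with fry 24, 1, 17 and 30. Without 1 library the KYSE-30 lists were 5 to 10 (10 without KYSE-410 siCT replicate 3; the 5 without KYSE-30 siCT replicate 1 share 2 with the 6, and the 1 passing fry shares 0) and the siCT lists 3 to 5 (5 without KYSE-410 siSHIP2 replicate 1). The cause was not tested.

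The excess of higher calls in KYSE-410 (61.3%) may come from the scaling, since the highest share over the other scalings was 48.7%, and the lowest 43.6%. Rounding up of low values is argued against as its whole cause, since the share was still 57% among genes of at least 10 CPM. That is below 61.3%, so a part played by low values is not excluded. The median change of all genes there was 0.07 in the deposited scale and -0.01 with TMM. Of 325 named gene results, 34 lost their call with TMM scaling, 56 without a filter, 12 with DESeq2, 10 and 9 with edgeR, 67 and 63 without KYSE-30 siSHIP2 or siCT replicate 1, 78 of 297 with each line alone and 47 of 309 with the replicate block, and 0 reversed in these settings. Replicate numbers do not appear to pair the libraries, since deviations of equal numbers correlated at -0.002, -0.236 and 0.221 in KYSE-410 and -0.161 in KYSE-30. Depth limits what can be said under about 0.15 CPM.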

Other observations

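The test of G2/M genes under other scalings was chosen only after the result was seen. Immediate early genes were among those that rose in KYSE-410. EGR3 rose from 0.833 to 11.9 CPM (log2 2.81), FOSB from 2.13 to 17.9 CPM (2.57), EGR1 from 24.5 to 77.3 CPM (1.61) and ATF3 from 14.7 to 42.4 CPM (1.46). Their list with heat shock genes did not pass, with 13 higher and 8 lower of 26 (camera adjusted p = 0.292), and 10 and 10 with TMM scaling. The p53 targets TP53INP1 (2.95 to 21.8 CPM, log2 2.52), BBC3 (1.1) and XPC (0.69) rose, in a list of 25 with 14 higher and 6 lower (camera adjusted p = 0.298), and 9 and 7 with TMM or relative log expression scaling. The pro-apoptotic PMAIP1 rose by 0.87 and the protective MCL1 by 0.44. Of growth factor genes, ERRFI1 (0.97), which restrains EGF receptor signalling, and AREG (0.88) rose, and the receptor gene MET fell from 283 to 143 CPM (-1.0). NDRG1 rose from 46.0 to 111 CPM (1.24) and the glycolytic GPI fell from 528 to 240 CPM (-1.15).

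In KYSE-30 some interferon-induced genes rose. IFIT1 went from 12.1 to 21.8 CPM (log2 0.80, limma adjusted p = 0.0228), OASL from 5.75 to 9.29 CPM (0.61, adjusted p = 0.0382) and OAS3 rose by 0.33 (adjusted p = 0.0387). The list had 6 higher and 0 lower of 32 by limma, with 9 higher and 2 lower when adjusted over the list alone, and did not pass (camera adjusted p = 0.0578). OASL and OAS3 lost their call with TMM scaling.

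Genes lower in both lines numbered 140 where independent lists would share 61.0, and a candidate explanation is that the siRNA lowers other transcripts through its seed, the short stretch that can pair with 3' untranslated regions as a microRNA does. The sequence of the siRNA was not among the sources used, so 7-base sequences were scanned without it. The leading 7-mer in KYSE-410, ATCAACA (z -13.6), is absent from the INPPL1 transcript, so a condition set in advance was not met, although its last base need not pair with the target. The next, CATCAAC (z -12.1), occurs there once and ranked 4 in KYSE-30, where ATCAACA ranked 128. Of 16148 7-mers scanned, 3499 occur in the INPPL1 transcript, so a match alone says little. KYSE-30 was led by TTACGTG (z -5.32), which is absent from that transcript and ranked 4950 in KYSE-410. Carriers of CATCAAC differed from length-matched genes by log2 -0.23 in KYSE-410, where the sequence was picked for its low carriers, and by -0.04 in KYSE-30 (permutation p = 1e-05 there, the smallest that 100000 permutations can give).

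Among the 132 searched genes lower in both lines, 17.4% carried CATCAAC (95% interval 11.9% to 24.8%), against 6.6% of length-matched genes. The core shared by these sequences, ATCAAC, was in 53%, against 21.4%. Both shares lean on the choice of sequences by their fall in KYSE-410. Genes lower in KYSE-30, a line not used for that choice, carried CATCAAC in 12.3%, against 7.1% of length-matched genes, and the core in 38.7%, against 22.6%. But 132 of these 284 genes are those lower in both lines. They hold 23 of the 35 carriers of CATCAAC and 70 of the 110 carriers of the core. The KYSE-30 shares thus lean on that choice as well, and genes lower in KYSE-30 only were not tested apart. Over all searched genes the number lower in both lines was 1.81 times that of independent lists (1.58 to 2.03). It was 1.63 times (1.42 to 1.86) among carriers of the core and 1.55 times (1.27 to 1.85) among genes lacking it, between the bounds of 1.3 and 2 set in advance. Genes lacking the core still shared 62 where independent lists would share 39.9, so core matches in the regions searched are not the whole of the excess. The values of 1.63 and 1.55 both lie below 1.81, and what part of the excess goes with seed matches is left open. CFL2, RAB15 and TXNDC12 carry a 7-base match, SSBP3 the core alone, and PSIP1, LAMC1, AKR1B10 and INPPL1 none. In KYSE-410 48.9% of carriers of the longest, 8-base site were called lower, against 23.0% of genes with no site, whose untranslated regions are shorter (median 799 bases against 3309). Of the named genes that fell most there, NPR3 and LAPTM5 carry that site and TGM2 a 7-base one, while KLHL24, which rose, also carries a 7-base one. In KYSE-30 the share called lower was 5.8% with the 8-base site and 5.1% or 3.3% with a 7-base one. It was 6.6% with the core alone and 1.7% with no site, so in KYSE-30 it did not follow the length of the match. Sequencing depth is argued against, since 100% of the 140 genes were still called lower in KYSE-410 on reads with the rounding undone, and 120 were in both lines. A shared response to the loss of SHIP2 stays open, as untested, because the siRNA was the only one analysed here.

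The fall of G2/M and mitosis genes in KYSE-410 was set against the same core and the scaling. The core was in 6 of 35 members, against 2.6 expected at their lengths, and these carriers had a median of -0.893, but the core was picked on falls in the same libraries. NRF2 targets had a like excess (8 of 28, against 4.1), with a median of -0.44 for carriers and -0.33 for the others, and so had FOXO targets (10 of 24 searched, against 6.1), whose carriers rose more (0.66 against 0.35). Carriers were also lower than the others among MYC (-0.33 and -0.25) and cholesterol (-0.405 and -0.284) genes, without an excess. Members lacking the core still had a median of -0.325, against -0.366 for the whole list, so core matches are argued against as the whole cause. Of the members called lower, 100% at the lowest were called lower under the other scalings. Those scalings all move the fold changes of KYSE-410 downward, so lower calls could hardly be lost and the test does not decide. The list median was -0.484 with TMM, -0.475 with relative log expression and -0.45 with upper quartile scaling. Whether the fall follows from SHIP2 or from another effect of the siRNA was not tested, and could be asked with the other siRNA.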
